A study of Mus musculus with 3 samples.

How the data were processed

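The series held 3 droplet libraries (10x Chromium 3' chemistry, v2) of dendritic cells from the mesenteric lymph nodes of C57BL/6 mice. The deposited tables held raw UMI counts per gene and barcode, made with Cell Ranger according to the submitters' processing notes, and the genome build and annotation were not given in the sources used here. Counts were whole numbers for 27998 features, of which 121 symbols were shared by more than 1 feature, and such features were kept apart by Ensembl ID. The 3 tables held 13206 barcodes: 4235 without SFB, 4365 with SFB and 4606 in the resident library, with 27874898, 34343225 and 45924871 UMIs. Cells were grouped by the sample names into 1 library per group. Immunoglobulin constant genes were not among the features, and reads were not used here.

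Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. The gene filter left out 140, 354 and 85 barcodes of the 3 libraries and the mitochondrial filter 34, 116 and 45, each barcode being counted once. Doublets were sought with Scrublet through scanpy 1.11.5 at an expected rate of 0.04 with its automatic threshold. It marked 2 cells in all (1, 1 and 0), far from that rate, so the call did not work and doublets were effectively not removed. The cells kept numbered 4060, 3894 and 4476, with 15562, 15971 and 15657 genes detected and median mitochondrial shares of 1.85%, 2.40% and 2.09%. In the shallowest library 50 CPM corresponded to more than 1000 UMIs, and the interval of each ratio shows the precision of rarer genes.

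All 3 libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and logged, 2000 variable genes (in at least 10 cells) were chosen per library and combined, and 30 principal components fed a graph of 15 neighbours that was split by the Leiden method (python-igraph 0.11.9, resolution 1.0, seed 1). A cluster took the name of the best of 15 marker lists if at least 3 of its markers were 2-fold above the mean of the other clusters, with 10 CPM added. It stayed unnamed if its 10 leading genes held more markers of another list than of the best one, even by a single gene, or if the best lists tied. Shallow clusters stayed unnamed if those 10 genes held no marker of the best list. In a library clustered alone, the mean was that of its own other clusters. The 31 clusters comprised 11 CCR7-high, 3 ILC3-like, 3 cDC1-like, 2 cDC2-like and 4 cycling clusters, 1 each of the monocyte or macrophage-like, pDC-like, B cell-like and T cell-like classes, and 4 unnamed clusters.

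With 1 library per group no test was possible and no p-value was computed. For 3 comparisons (SFB in the whole migratory libraries, SFB within classes of at least 50 cells in both libraries, and resident against migratory DC with SFB) counts were summed over cells and scaled to CPM by the total of all genes. Each ratio carries an exact conditional 95% interval, and each share of cells an exact binomial 95% interval. Where 0 cells were found, the share said to be allowed is that of 3 cells, which lies below the upper bound of the binomial interval. A gene with 0 counts in one library was set against a floor of 3 counts and given as a bound, and genes of 1 to 3 counts kept their ratio and interval. This departed from the written design, which gave every gene under 3 counts as a bound. Genes with at least 50 CPM in either library and a 2-fold ratio were counted.

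Named genes followed a fixed rule: the 15 highest and 15 lowest ratios of each comparison (8 and 8 per class), up to 4 members per list, and 23 genes named always, with both features of the symbol Itgam. Ribosomal, mitochondrial, predicted, immunoglobulin and T cell receptor segment genes were left out of the naming. The reading of this rule that kept Gm2a and Jchain was settled after the tables were seen. Genes were reported with a warning where 2 cells held most UMIs, and genes were marked for such a check when 20% of at least 50 UMIs lay in 2 cells. The 24 gene lists were described by their members with at least 20 CPM, the number past 1.5-fold, the median log2 ratio and its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression.

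For the shares of cells with a UMI, 20 genes were fixed and every cell was thinned to 2800 UMIs, the lowest 10th percentile of depth among the libraries rounded down. The pDC-like cells served as background, on the untested assumption that they lack the genes compared. Sex was read from Xist and Y-linked transcripts per cell: Xist alone in 24.7%, 27.5% and 28.2% of cells of the 3 libraries, Y-linked transcripts alone in 35.5%, 42.5% and 43.1%, and both in 4.19%, 5.70% and 6.01%.

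The comparisons, lists, markers and alternatives were fixed before the data were examined. The alternatives were all deposited barcodes, a stricter filter (1000 genes, 5% mitochondrial UMIs), doublets kept, TMM scaling (edgeR 4.0.16), median-ratio scaling, totals without ribosomal, mitochondrial and immunoglobulin genes, equal weight per cell, thinned cells, minima of 10 and 200 CPM, dendritic clusters only, one mix of clusters (at least 20 cells in both libraries), resolutions of 0.5 and 2.0, another seed, 1000 variable genes, each library clustered alone, and no thinning or thinning to 1400 UMIs. Leaving out the 4% of cells with the highest doublet scores, leaving out the cells under 1% mitochondrial UMIs, using CCR7-high cells alone for the shares, and leaving the cluster led by Il6 out of the CCR7-high class were chosen after seeing the data.

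The ratio and list code was tested on simulated data. Genes set 2.2-fold apart passed the 2-fold rule in 50 of 50 cases for the SFB comparison and 49 of 50 for the resident one, genes set 1.5-fold apart in 0 of 50 in both, and unchanged genes in 0 of 1768 and 0 of 1983. A simulated list of 20 genes at 1.5-fold had median log2 ratios of 0.58 and 0.59. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3. Counts of genes past 2-fold in the pDC-like, monocyte or macrophage-like and ILC3-like classes were left out because few cells make them up, and cluster-defining genes were used for naming only.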

Results

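Dendritic cells (DC) of the mouse mesenteric lymph node were profiled by droplet single-cell RNA sequencing in 3 libraries, 1 per group. The groups were gut-derived migratory DC of mice without segmented filamentous bacteria (SFB), migratory DC of mice with SFB, and lymph-node-resident DC of mice with SFB. SFB are commensals that attach to the ileal epithelium and are known for inducing Th17 cells, and the series set out to compare the 2 DC populations in naive and colonized animals. After the cell filter the library without SFB held 4060 cells and 27661490 unique molecular identifiers (UMIs), with a median of 6151 UMIs and 1622 genes per cell. The migratory library with SFB held 3894 cells and 33687990 UMIs (medians of 8338 UMIs and 1920.5 genes), and the resident library 4476 cells and 45772300 UMIs (medians of 9065 UMIs and 2312 genes). No group had a replicate library, so no difference below was tested, and every 95% interval covers counting error only. Per the labels, all 3 samples carried the same gavage and sorting text (CD11c-positive, MHC class II-high cells, day 5 after gavage), so the groups rest on the sample names alone.

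CCR7-high DC, the mature cells that carry antigen to the node, made up most of both migratory libraries and almost none of the resident one. The CCR7-high DC-like class held 77.8% of cells without SFB (95% interval 76.5 to 79.1), 84.8% with SFB (83.7 to 85.9) and 0.335% in the resident library (15 cells). The resident library was instead split between cDC2-like cells (32.5%, 31.1 to 33.9), cross-presenting cDC1-like cells (27.3%, 26.02 to 28.65) and cycling cells (24.7%). In the migratory libraries cDC2-like cells were 1.92% without and 0.873% with SFB, cDC1-like cells 1.38% and 0.616%, and cycling cells 0.936% and 0.616%. Plasmacytoid DC-like (pDC-like) cells formed 1.48%, 2.08% and 1.18% of the library without SFB, the migratory library with SFB and the resident library, and monocyte or macrophage-like cells 2.17%, 1.57% and 2.88%. Cells named by markers such as Il7r and Il22, called ILC3-like here although some antigen-presenting cells share markers of this class, formed 3.60%, 4.31% and 0.402%. B cell-like cells numbered 69 without SFB (1.70%), 2 in the migratory library with SFB (0.0514%) and 0 in the resident library, which allows up to 0.0670%. The 2 cells with SFB held 883 and 871 UMIs of the plasma cell gene Jchain, beside at most 19 in a cell without SFB. They thus differed from the 69 in this gene and may be plasma cells. T cell-like cells, a cluster led by Hes1, Arg1, Gzma and Cd3g, numbered 13, 26 and 25. No cluster took the plasma cell, NK cell or ILC1, neutrophil, basophil or mast cell, stromal or endothelial name under the naming rule, which does not bound these cells: an unnamed cluster led by S100a8, S100a9 and Mcpt8 held 5, 11 and 9 cells. Clusters left unnamed held 8.67%, 4.39% and 10.1% of cells. The largest, led by Mdk, Ryr3 and H2-M2, was closest to CCR7-high DC and held 6.13% of cells without and 2.52% with SFB. A shallow one closest to the same class held 2.02% and 1.41%. The gap between the migratory CCR7-high DC-like shares thus rests partly on the naming rule. The second largest, led by Rasgef1b, Il1r2 and Nr4a1, was closest to cDC2 and held 8.2% of resident cells. The depth per cell differed between libraries, and clustering each library alone placed 46.2% and 30.1% of migratory cells in the CCR7-high DC-like class. The cDC2-like share of the resident library was then 5.29%. In that setting clusters were named against the other clusters of the same library, so these shares may follow from the naming rule.

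**Figure D1:**
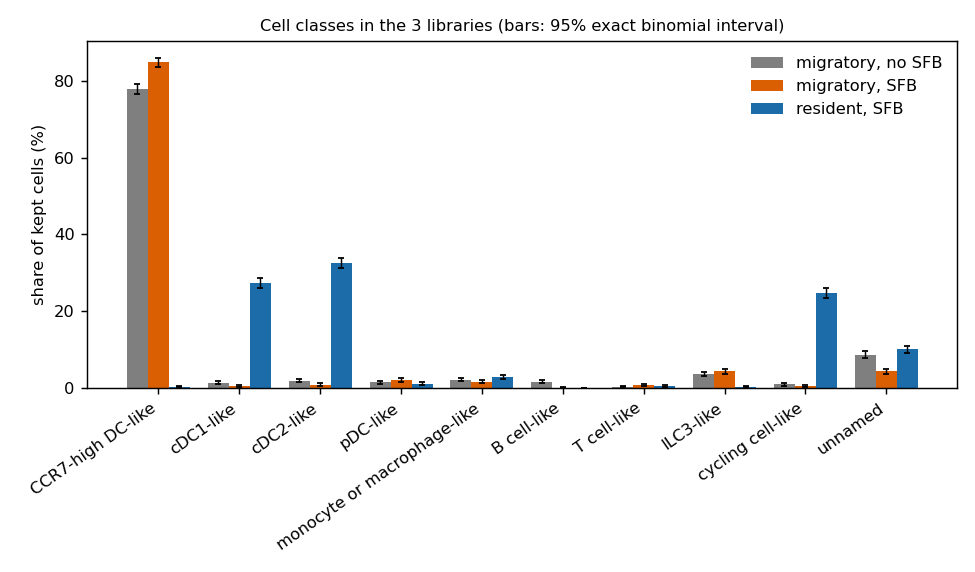
Share of kept cells (%) in each cell class for the library without SFB (grey), the migratory library with SFB (orange) and the resident library (blue), with 95% exact binomial intervals. In this joint clustering CCR7-high DC-like cells fill the migratory libraries (77.8% and 84.8%), while cDC1-like, cDC2-like and cycling cells fill the resident one. With each library clustered and named alone the CCR7-high DC-like shares were 46.2% and 30.1%, and the resident cDC2-like share 5.29%.

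The comparison of resident with migratory DC after colonization asks which programmes separate the populations. Resident cells were rich in the genes of immature, cDC1 and dividing DC, and migratory cells in those of the CCR7 maturation programme. Rab7b, a lysosomal GTPase, stood at 144 CPM (UMIs scaled to the library total) in the resident library and 2.49 CPM in the migratory one (57.9-fold higher, 95% interval 46.7 to 72.7). Naaa, a lysosomal amidase of cDC1, was 57.0-fold higher in the resident library, and Xcr1, the chemokine receptor that marks cDC1, 29.5-fold higher (7.33 and 216 CPM). In the other direction, Ccl22, which draws CCR4-bearing T cells, stood at 1796 CPM in the migratory library and 8.04 CPM in the resident one (223-fold lower), Ccr7 was 58.0-fold lower in the resident library and the actin bundler Fscn1 65.2-fold lower (3179 and 48.7 CPM).

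Of 2688 genes with at least 50 CPM in either library, 667 were at least 2-fold higher and 450 at least 2-fold lower in the resident library. The median gene was 0.31 higher on the log2 scale, a shift that became -0.09 under TMM scaling and -0.11 under median-ratio scaling. The split of higher and lower genes was 440 to 599 under TMM and 390 to 570 under median-ratio scaling, so the surplus of higher genes depended on the scaling, while the sign of the large ratios named here did not. The 2 libraries shared little of their cell mix: only 5 clusters, with 7.37% of migratory and 20.4% of resident cells, held enough cells of both, and at one mix of these 34 genes were higher and 88 lower. The genes with the next highest ratios in the resident library were Gcsam (45.4-fold), Bex6 (33.1-fold), Cd244 (31.7-fold), March1 (28.2-fold), Unc119, Rgs18 and Tm6sf1, together with the mitotic genes Rrm2 (32.4-fold), Cdca3, Ccnb2, Ube2c (lower at one mix of clusters, log2 -0.65) and Birc5 (24.9-fold). The lowest in the resident library after Ccl22 were Nudt17 (151-fold), the T cell co-stimulators Tnfrsf4 (143-fold) and Tnfrsf9 (112-fold), Sema6d, Lad1, Zmynd15, Ccl17 (480 and 4.19 CPM), Cacnb3, Socs2, Dnah2, Adcy6, the tetraspanin Cd63 (947 and 10.6 CPM) and Clu. Jchain was also among them (135-fold), but 2 B cell-like cells held 92.7% of its 1892 UMIs in the migratory library.

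**Figure D2:**
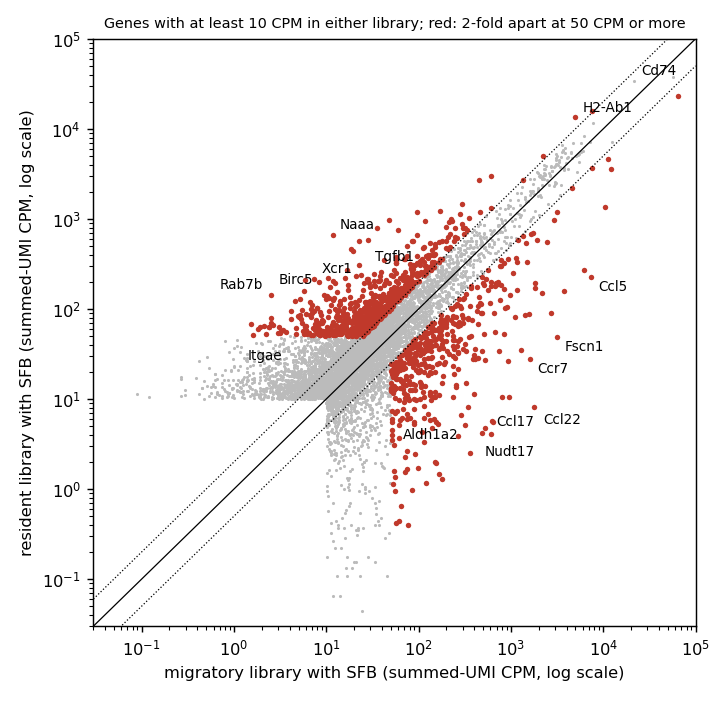
Summed-UMI CPM of each gene with at least 10 CPM in either library, in the migratory (x axis) and the resident library with SFB (y axis), both on log scales; genes with 0 counts in one library are not drawn, the solid line marks equal CPM and the dotted lines 2-fold. Red points are the 667 higher and 450 lower genes, with Naaa, Rab7b and Xcr1 above and Ccl22, Nudt17 and Ccr7 below the lines.

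The gene lists drew the same line between the libraries. Of 27 measured members of the CCR7 maturation programme, 26 were at least 1.5-fold lower and 1 higher in the resident library (median log2 ratio -4.13, below all 10000 random lists of the same size and mean expression). Of 17 cDC1 genes 16 were higher (median 4.04, percentile 100), among them Tlr3 (55.2-fold), the receptor for double-stranded RNA. Of 18 genes of immature or resident DC 13 were higher and 1 lower (median 2.65, percentile 100; Plbd1 22.4-fold), and of 11 cDC2 genes 8 were higher and 2 lower (median 2.14, percentile 100), with Clec4a2 15.4-fold and Ccr2 8.16-fold higher and Tnip3 at 0.0768 of its migratory level. The marker genes Cd8a (5.96-fold), Sirpa (3.57-fold) and Cd4 (2.45-fold) were higher in the resident library. Itgam (CD11b) was 10.5-fold higher for the feature ENSMUSG00000030786 (29 and 413 counts) and 4.31-fold (7 and 41 counts) for the feature ENSMUSG00000108596 that shares its symbol. Of 22 cell cycle genes 19 were higher and 0 lower (median 2.92, percentile 100).

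Antigen presentation split by class. Of 18 MHC class II genes 9 were higher in the resident library and 5 lower (median 0.62, percentile 98.2), the higher ones including H2-Ob (9.40-fold), H2-DMb1 (6.93-fold), H2-Ab1 (2.74-fold) and Cd74 (1.58-fold), while the protease gene Lgmn was lower (0.125). MHC class I genes were mostly lower, 14 of 18 against 2 higher (median -0.97, percentile 0.04), such as H2-K1 at 0.333 and the proteasome activator Psme2 at 0.222. Of 12 co-stimulation and co-inhibition genes 9 were lower and 3 higher (median -2.11, percentile 0.01), from Cd70 (784 and 5 counts) and Cd40 (0.142) to Havcr2, which was 20.5-fold higher, and Cd86 was 1.96-fold higher. Of 20 NF-kB targets 16 were lower and 1 higher (median -1.39, percentile 0), Relb at 0.199 among them.

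Metabolic and stress lists differed as well, except oxidative phosphorylation, whose median (0.38) was close to that of all genes (0.31). Of 15 cholesterol biosynthesis genes 13 were lower and 0 higher (median -1.25, percentile 0.01; Idi1 at 0.119), whereas 7 of 13 glycolysis and hypoxia genes were higher and 1 lower (median 0.93, percentile 98.1), with Ldha at 74.0 and 495 CPM. Of 18 unfolded protein response genes 10 were higher and 4 lower (median 0.72, percentile 96.9; Pdia6 6.10-fold and Hsp90b1 5.20-fold higher), and of 24 oxidative phosphorylation genes 9 were higher and 1 lower (median 0.38, percentile 84.6; Cycs 3.52-fold). Immediate early and dissociation genes were higher for 10 and lower for 1 of 19 members (median 0.72, percentile 98.0), including Nr4a1 (10.8-fold), Fos (6.49-fold) and Ier2 (4.26-fold). The interferon-gamma-induced list had 6 of 10 members lower and 4 higher (median -1.76, percentile 0), with Gbp2 at 0.0241 and Gbp5 at 0.0540 but Cxcl9 8.35-fold higher, a direction that turned at one mix of clusters (log2 -0.23). Interferon-stimulated genes were mixed, 6 higher and 7 lower of 16 (median 0.03, percentile 13.4), and their median was negative under TMM (-0.70) and median-ratio (-1.11) scaling; Mx1 stood at 0.112 and Rtp4 was 5.01-fold higher.

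Genes tied to retinoic acid, TGF-beta and Th17 induction went both ways. Aldh1a2, the enzyme that makes retinoic acid, was 61.2-fold lower in the resident library (314 and 5.13 CPM) and Itgb8, which activates TGF-beta, was 136-fold lower (701 and 7 counts), while Tgfb1 was 4.46-fold and Itgae (CD103) 23.4-fold higher. The gut CD103 and retinoic acid list therefore had 3 members higher and 3 lower of 6 (median -0.60, percentile 5.63), as did the 6 measured Th17-linked cytokine genes (median -0.37, percentile 14.99). Il6 stood at 0.159 and Il12b at 0.132 of the migratory level, Isg15 at 0.369, and Il23a had 36 migratory counts and 1 resident count (ratio 0.0204, 95% interval 0.000504 to 0.121), whereas Il1b was 2.01-fold higher. Saa3 had 2 and 9 counts (ratio 3.31, 95% interval 0.686 to 31.5). Of 12 chemokine and receptor genes 6 were higher and 5 lower (median 0.64, percentile 92.9), the lower ones including Ccl5 (32.1-fold). Of 27 cytoskeleton and migration genes 7 were higher and 11 lower (median -0.19, percentile 3.13), with Anxa3 at 0.0291 and Anxa1 16.4-fold higher. The antimicrobial list had 3 of 5 higher and 1 lower (median 1.25, percentile 93.8; Tlr11 3.09-fold and Ly96 at 0.166), and the apoptotic cell uptake list 2 higher and 2 lower of 5 (median 0.18, percentile 36.3; -0.12 under TMM and -0.13 under median-ratio scaling). The 3 measured sex-linked transcripts had a median of -0.13 (percentile 25.4), and 0 members of the epithelial cargo list were measured.

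The comparison of migratory DC with and without SFB asks how the cells that reach the node differ with colonization. The library with SFB was higher in the lipid carrier gene Fabp5, the T cell-attracting chemokine genes Ccl17 and Ccl22, interferon-linked Ifitm1 and the inflammatory cytokine genes Il1b and Il6. Fabp5 stood at 692 CPM without and 1837 CPM with SFB (2.65-fold, 95% interval 2.61 to 2.70), Ccl17 at 204 and 480 CPM (2.35-fold, 2.28 to 2.43) and Ifitm1 at 21.3 and 104 CPM (4.90-fold, 4.49 to 5.35). Il6, which steers T cells to the Th17 fate, stood at 2.82 and 14.6 CPM (5.18-fold, 4.07 to 6.66, from 78 and 492 counts, most of the latter in a single small cluster). Il23a, a subunit of the cytokine that sustains Th17 cells, had 1 count without and 36 with SFB (29.6-fold, 4.98 to 1200).

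Few genes passed the size rule. Of 2055 genes with at least 50 CPM, 8 were at least 2-fold higher with SFB and 9 at least 2-fold lower, and the median log2 ratio was -0.01; under TMM scaling the split was 11 to 6. Besides Fabp5, Ccl17 and Ifitm1, the higher genes were the stress genes Gadd45g (3.61-fold) and Hspa1a (127 and 358 CPM, 2.82-fold), Selm (2.59-fold), the AP-1 family gene Batf (2.08-fold) and Jchain. Jchain, a joining chain gene of plasma cells, had the highest ratio (22.8-fold, 17.9 to 29.5), but without the 2 cells that held 92.7% of its UMIs it stood at 4.10 CPM with SFB. The next highest were Jun (1.98-fold), Ptpn1 (1.92-fold), S100a6 (1.85-fold), Hist1h2ap, Ccnd2 (1.80-fold), Il1b (76.2 and 135 CPM, 1.77-fold) and Ifitm2 (1.75-fold). The lower genes were the endosomal GTPase Rab21 (95.01 and 38.4 CPM, 2.47-fold lower), Cdk2ap1 (2.36-fold), Plbd1 (2.34-fold), the zinc transporter Slc39a1 (2.30-fold), Asb2 (2.29-fold), the lysosomal lipid cofactor Gm2a (2.17-fold), Cbx3, Atxn1 and Ppt1 (2.01-fold). Below 2-fold followed Alox5ap, Tmem158, Abhd2, Serinc3, the interferon-gamma receptor gene Ifngr1 (74.0 and 42.2 CPM) and Ccnd1 (1.73-fold lower).

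**Figure D3:**
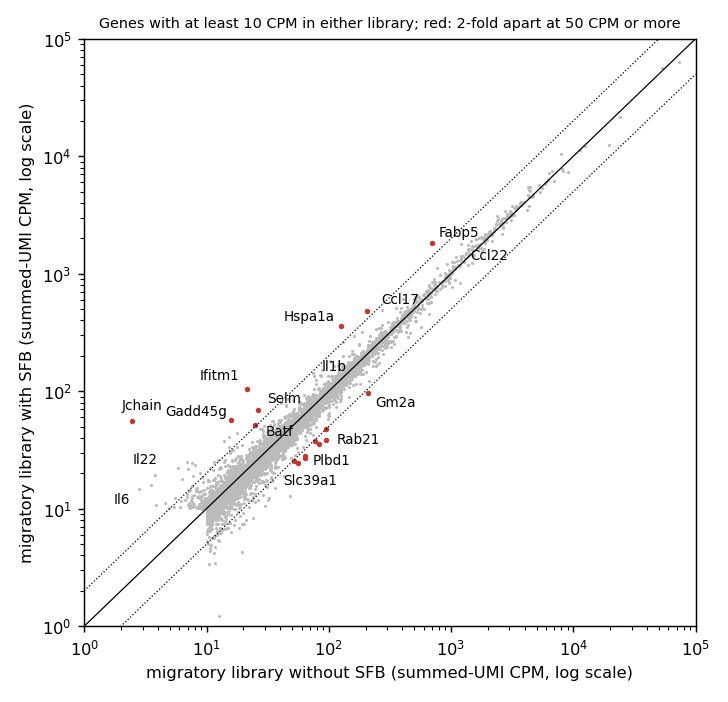
Summed-UMI CPM of each gene with at least 10 CPM in either library, in the migratory library without SFB (x axis) and with SFB (y axis), both on log scales; genes with 0 counts in one library are not drawn, the solid line marks equal CPM and the dotted lines 2-fold. Red points are the 8 higher and 9 lower genes; Il22 and Il6 lie above the upper line at under 50 CPM.

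Cytokine, interferon and co-stimulation genes leaned higher with SFB. Of 5 measured Th17-linked cytokine genes 1 was at least 1.5-fold higher and 0 lower (median log2 ratio 0.30, percentile 99.9 among random lists), Il12b at 1.30-fold and Ebi3 at 1.23-fold, while Tgfb1 stood at 0.740 of its level without SFB. The 7 interferon-gamma-induced genes had a median of 0.36 (percentile 99.99) with none past 1.5-fold, such as Socs1 (1.46-fold), Gbp5 (1.45-fold) and Gbp2 (245 and 341 CPM). Of 13 interferon-stimulated genes 1 was higher and 0 lower (median 0.18, percentile 99.97), Zbp1 at 1.92-fold and Isg15 at 1.48-fold, and Usp18 stood at 0.731. Co-stimulation and co-inhibition genes had 1 higher and 1 lower of 11 (median 0.20, percentile 99.91), with Cd70 at 1.53-fold, Cd40 at 1.35-fold, Cd86 at 1.30-fold and Icosl at 0.605. The 3 measured antimicrobial genes had a median of 0.36 (percentile 99.4; Myd88 1.56-fold), and the 20 NF-kB targets of 0.04 (percentile 82.9), with Tnfaip2 at 1.45-fold and Tnfaip3 at 0.722.

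In the whole libraries, genes of cDC lineages and of the apoptotic cell uptake list leaned lower with SFB. Of 8 cDC1 genes 3 were lower and 0 higher (median -0.38, percentile 0.01), with Xcr1 2.75-fold and Naaa 2.70-fold lower. The cDC1-like share was itself lower with SFB (1.38% and 0.616% of cells), and within CCR7-high DC-like cells 0 of 5 cDC1 genes passed 1.5-fold (median -0.24). Of 12 genes of immature or resident DC 3 were lower (median -0.18, percentile 1.39). Of 9 cDC2 genes 3 were lower and 1 higher (median -0.20, percentile 3.61), with Sirpa at 0.643 and Klf4 at 1.53-fold. The cDC2-like share was lower too (1.92% and 0.873%), and within CCR7-high DC-like cells the list had a median of 0.62 over 4 measured genes. Of the 4 apoptotic cell uptake genes measured in the whole libraries 2 were lower and 0 higher (median -0.45, percentile 0.08), with Abcg1 at 0.640 and Cd36 at 0.650. MHC class II genes had 1 of 17 lower (median -0.10, percentile 0.98), H2-Ob at 0.550, H2-Ab1 at 0.917 and Cd74 at 0.903. The 18 MHC class I genes had a median of -0.01 (percentile 14.0; H2-M2 0.680) and the 27 CCR7 programme genes of -0.03 (percentile 2.42; Ccl22 1.49-fold, Pdcd1lg2 1.48-fold, Ccr7 0.872); both medians were positive under TMM (0.07 and 0.05). Chemokine and receptor genes had 1 higher and 3 lower of 9 (median -0.20, percentile 0.855; 0.03 under TMM), Ccl9 at 0.539 and Ccl6 at 0.603. The gut CD103 and retinoic acid list had 0 of 5 past 1.5-fold (median -0.17, percentile 10.96), and Aldh1a2 stood at 319 and 314 CPM (ratio 0.984, 95% interval 0.956 to 1.01), with a sign that turned under TMM (log2 0.06). Cd8a stood at 0.897 and Cd4 at 0.531 of the level without SFB, and Itgam at 0.541 (44 and 29 counts) and 1.44 (4 and 7 counts) for its respective features ENSMUSG00000030786 and ENSMUSG00000108596. No difference beyond counting error was detectable for Itgae (ratio 1.28, 0.881 to 1.88), Itgb8 (0.948, 0.849 to 1.06) or Cxcl9 (0.986, 0.867 to 1.12), and Saa3 had 2 counts in each library.

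The medians of the remaining lists were close to that of all genes, though several of them had high percentiles among random lists. Of 26 cytoskeleton and migration genes 3 were higher and 1 lower (median 0.11, percentile 97.1), namely S100a6, Lgals1 (1.54-fold) and Anxa2 (1.52-fold), and Actb (19516 and 12559 CPM). Of 17 dissociation and immediate early genes 3 were higher and 1 lower (median 0.06, percentile 94.4), with Hspa1b at 2.64-fold and Nr4a1 at 0.576. Cholesterol biosynthesis (15 genes, median 0.08, percentile 99.0; Mvk 1.37-fold), glycolysis and hypoxia (10 genes, 0.04, percentile 85.1; Pgk1 1.24-fold), oxidative phosphorylation (24 genes, 0.04, percentile 68.5), the unfolded protein response (16 genes, 0.05, percentile 93.8; Herpud1 0.671) and the cell cycle (7 genes, -0.11, percentile 10.6; Stmn1 0.688) had 0 members past 1.5-fold. The 3 sex-linked transcripts had a median of -0.04 (percentile 47.0; 0.05 under TMM), with Xist at 265 and 259 CPM, and both libraries held cells of both sexes. The epithelial cargo list had 0 measured members.

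Within the CCR7-high DC-like class Ifitm1 and Il1b stood further apart than in the whole libraries. Ifitm1 was 8.77-fold higher with SFB (11.2 and 98.5 CPM, 95% interval 7.69 to 10.0), Fabp5 2.73-fold, Il1b 2.30-fold (47.4 and 109 CPM, 2.14 to 2.47), Ccl17 2.14-fold (246 and 525 CPM) and Il6 4.82-fold (3.22 and 15.6 CPM, 3.74 to 6.30). Il23a had 1 and 36 counts (26.4-fold, 4.45 to 1070). For Il6 and Il23a the difference lay in a small cluster led by Il6 and Il12b (cluster 23, 5 and 71 cells), which held 77.8% of the Il6 and 91.7% of the Il23a UMIs of the class with SFB. It held 10 of 70 Il6 UMIs without SFB and 358 of 460 with SFB, and as it is led by Il6 the cells left outside it do not show whether Il6 differed. Il1b (2.30-fold) and Ccl17 (1.96-fold) stayed higher without that cluster. The largest clusters of the 3160 and 3303 cells were 3 and 0 without SFB and 0 and 1 with SFB, and cluster 3 held shallow cells of low mitochondrial content, so part of the contrast lies between clusters. With 5 CPM added, the log2 ratio of Ifitm1 was 1.78 in cluster 0, 0.740 in cluster 1 and 1.15 in cluster 3. Across the CCR7-high clusters compared it ranged from 0.188 to 3.28 (cluster 17), beside 2.29 in the whole libraries with no CPM added. When each library was clustered alone, Il6, Il23a and Selm were lower with SFB in the class (log2 -0.42, -1.38 and -0.13). Clusters were then named within each library and the class held fewer cells, so the naming rule may give this turn.

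Of 1990 genes in the class 13 were at least 2-fold higher with SFB and 5 lower (median log2 ratio -0.02). The others named were Gadd45g (4.79-fold), Hspa1a (3.07-fold), the calcium-binding S100a6 (2.83-fold), Jun (2.71-fold), Plac8 (2.47-fold) and Selm (2.33-fold) on the higher side, and Rab21 (0.392), Slc39a1 (0.424), the lysozyme Lyz1 (0.426, though higher in 6 of 8 CCR7-high clusters), Cdk2ap1 (0.432), Atxn1 (0.451), Abhd2, the perforin-like Mpeg1 (0.519) and Tmem158 on the lower side. Of 12 interferon-stimulated genes 3 were at least 1.5-fold higher and 0 lower (median 0.22, percentile 99.98), namely Zbp1 (1.97-fold), Trim30a and Ifi27l2a (1.75-fold), and of 7 interferon-gamma-induced genes 1 was higher (median 0.32, percentile 99.87; Socs1 1.56-fold). Co-stimulation genes had a median of 0.22 over 10 (percentile 99.95; Cd86 1.55-fold, Icosl 0.591), the 5 Th17-linked cytokine genes of 0.23 (percentile 99.53) and the 10 glycolysis genes of 0.18 (percentile 99.75; Ldha 1.48-fold). The 4 measured cDC2 genes had a median of 0.62 (percentile 99.94), with Klf4 2.33-fold and S100a4 1.75-fold higher. Of 15 dissociation and immediate early genes 4 were higher (median 0.18, percentile 99.94). The CCR7 programme itself had a median of -0.14 over 27 genes (percentile 0.015), Ccr7 at 0.809 but Ccl22 at 1.36-fold, and the 3 apoptotic cell uptake genes of -0.62 (percentile 0.03). MHC class II genes had a median of 0.10 here (percentile 87.9; H2-DMb1 1.30-fold, H2-Ab1 1.09-fold). Cxcl9 was 2.88-fold higher within the class (3.36 and 9.67 CPM), and Aldh1a2 stood at 0.909 in the class although it was higher with SFB in each of the 8 CCR7-high clusters compared. Some ratios differed with the sex of the cells, and H2-Ab1 (0.841 in cells with Xist UMIs alone and 1.17 in cells with Y-linked UMIs alone) and Nr4a1 (0.284 and 1.10) lay on both sides of 1. Il6 was 7.19-fold and 3.74-fold higher in these cells. In cells with Xist UMIs alone Klf4 was 1.13-fold (0.852 to 1.496), Ccl17 1.56-fold, Gbp5 1.01-fold and Il12b 2.71-fold higher, and in cells with Y-linked UMIs alone 3.01-fold, 3.02-fold, 1.47-fold and 1.08-fold.

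**Figure D4:**
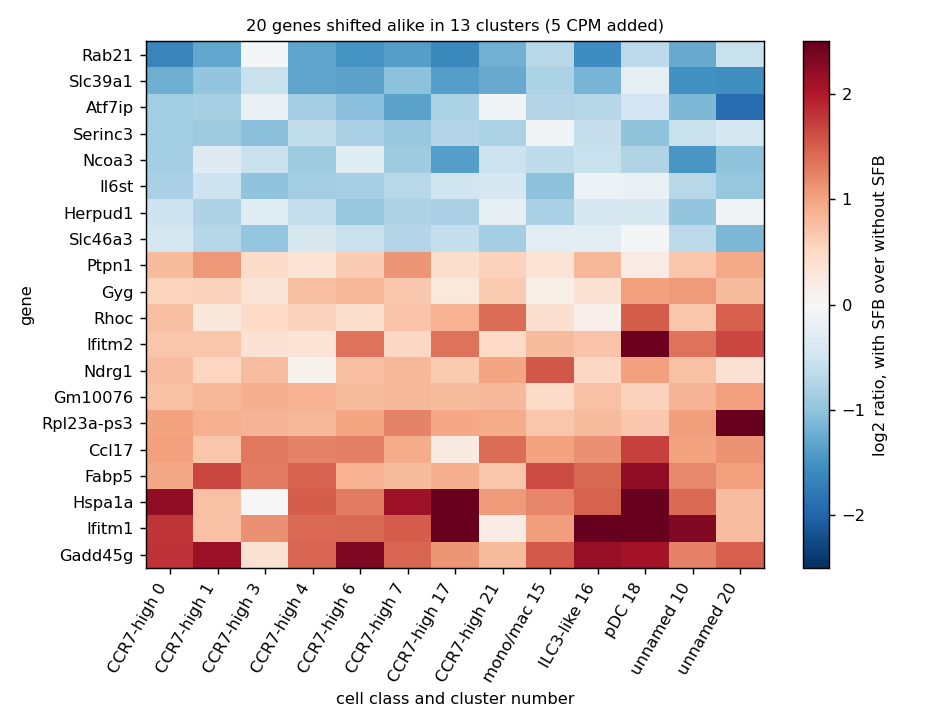
Log2 ratio (library with SFB over library without, 5 CPM added to both) of 20 genes, columns being clusters with their class and number. The genes were chosen for a ratio of one sign in all 13 clusters with enough cells and a median ratio of at least 1.5-fold. By that choice the 8 blue genes, such as Rab21, were lower and the 12 red genes, such as Ccl17, Fabp5 and Gadd45g, higher with SFB in each cluster. Values were close to 0 for Hspa1a and Rab21 in cluster 3.

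The smaller classes showed larger ratios from fewer counts. Among ILC3-like cells (146 without and 168 with SFB), Epcam was 10.6-fold higher with SFB (11 and 129 counts, 95% interval 5.72 to 21.7), Ly6a 6.40-fold, Selm 5.41-fold and Gadd45g 4.31-fold, followed by Prg2, Crem and Clu. The class pooled 3 clusters with different leading genes, and in the largest (cluster 16) the log2 ratio was 1.28 for Epcam, 1.06 for Selm, 0.20 for Clu and -0.56 for Prg2. Il22, which induces epithelial defence genes, was 5.41-fold higher (101 and 606 counts, 4.37 to 6.75), but in the whole libraries 2 cells held 55.8% of its UMIs without SFB and 34.97% with SFB. Both Il22 and Ly6a were lower with SFB when each library was clustered alone. Retnla had 59 and 0 counts (at least 21.8-fold lower against a floor of 3 counts), with 59 of the 63 UMIs of the library without SFB in 2 cells. Rab21 (0.288), Erdr1 (0.319), Ppt1, the growth factor gene Pdgfa (0.384), Spry2, Dnajc9 and Alox5ap were also lower, but Dnajc9 turned with all barcodes and at resolution 2.0. Of 12 cDC1 genes 7 were lower and 1 higher in this class (median -0.78, percentile 0), and of 14 genes of immature or resident DC 6 were lower and 0 higher (median -0.43, percentile 0). The cDC1-like share of the library was itself lower with SFB (1.38% and 0.616%). Of the ILC3-like cells of the 3 libraries 13.55% were among the top 4% of doublet scores. Free RNA or doublets were not tested as the source of these values.

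Among monocyte or macrophage-like cells (88 and 61), interferon-stimulated genes were higher with SFB in 17 of 21 and lower in 0 (median 1.11, percentile 100). Interferon-gamma-induced genes were higher in 8 of 10 and lower in 1 (median 0.87, percentile 99.98), and antimicrobial genes higher in 6 of 10 (median 0.81, percentile 99.78). The dissociation and immediate early list was higher in the same cells (10 of 19 higher, 0 lower, median 0.67, percentile 100). Igfbp7, Ly6a and Ifi205 were 15.1-fold, 13.6-fold and 13.2-fold higher, Gpnmb 19.3-fold with 70.4% of its UMIs in the library with SFB in 2 cells, and Igfbp4 had 1 and 31 counts (43.9-fold, 7.31 to 1789). In the whole migratory library with SFB 2 cells held 30 of 89 Igfbp4 and 32 of 99 Igfbp7 UMIs. If these cells lie in this class, they give most of the Igfbp4 ratio. The stromal matrix gene Dcn (0 and 79 counts, at least 37.3-fold), Gpx3 (0 and 52, at least 24.5-fold) and Clec3b (0 and 50, at least 23.6-fold) were higher too, but 2 cells held 84.9%, 78.5% and 90.7% of their UMIs in the library with SFB. The lectin genes Mgl2 (61 and 1 counts, ratio 0.0232, 0.000578 to 0.134) and Cd209a (117 and 7 counts, 0.0847), and Itgb7, Adam23, Cdk2ap1, Notch2, Gtf2e2 and Erdr1, were lower, and MHC class II genes had 4 of 18 lower and 1 higher (median -0.40, percentile 0). In the whole library without SFB 2 cells held 30 of 89 Mgl2 UMIs.

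Among pDC-like cells (60 and 81), 25 of 27 CCR7 programme genes were at least 1.5-fold higher with SFB and 0 lower (median 1.07, percentile 100), and so were 9 of 12 co-stimulation genes, with 1 lower (median 1.02, percentile 99.97). Dissociation and immediate early genes were higher there too (8 of 17, 0 lower, median 0.47, percentile 99.99). Hspa1a was 9.36-fold higher (11 and 157 counts), Arhgap31, Car2 and Hist1h2ap 8.46-fold, 8.19-fold and 8.08-fold, H2-M2, Ifitm2 and Fas 7.21-fold, 7.10-fold and 6.72-fold, and Il15ra had 0 and 37 counts (at least 8.08-fold). Eed (0.171), the chemokine receptor gene Ccr2 (155 and 35.4 CPM), Fcrla (0.286), Fam117a, Pdcd2, Gpaa1, Supt16 and Ap3s2 were lower, and of 17 interferon-stimulated genes 7 were lower and 2 higher (median -0.47, percentile 0.56). CCR7-high cells filled the migratory libraries and 15.5% of pDC-like cells of the 3 libraries were among the top 4% of doublet scores, and free RNA or doublets were not tested as the source of these values.

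Shares of cells with a UMI were compared after thinning every cell to 2800 UMIs. Ccl17 was found in 15.1% of cells without SFB, 26.8% with SFB and 0.319% of the resident library (22.7%, 45.5% and 0.693% without thinning), and Ccl22 in 63.0%, 73.5% and 0.684% (75.2%, 88.4% and 1.47%). Il1b was found in 11.2%, 18.8% and 27.7% (16.9%, 33.2% and 46.9%) and Aldh1a2 in 40.6%, 39.3% and 1.53% (57.4%, 63.1% and 4.2%). Il6 was found in 0.656%, 1.92% and 0.479% of cells (1.33%, 3.85% and 1.32%). The pDC-like cells were taken as background on the untested assumption that they lack these genes. Their shares without and with SFB were 1.69% and 16.05% for Ccl17, 27.1% and 54.3% for Ccl22, and 1.69% and 8.64% for Il1b. For Aldh1a2 the pDC-like shares were 6.78% and 11.1%, and for Il6 0% (0 of 59 and 0 of 81 cells, which allows 5.08% and 3.70%). All thinned cells had 2800 UMIs; without thinning the median depths of pDC-like cells of the 3 libraries were 6666, 6872 and 5642 UMIs beside 6151, 8338 and 9065 for all cells. The pDC-like shares of Ccl17, Ccl22 and Il1b were thus themselves higher with SFB, and the limits on Il6 exceed its shares. Free RNA, doublets and expression by the pDC-like cells themselves were not told apart as the source of these pDC-like shares.

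Among the other genes, Itgae marked 9.07% of resident cells (23.1% without thinning) beside 3.77% of resident pDC-like cells, and 0.464% and 0.427% of migratory cells, where 0 pDC-like cells had it. Cxcl9 was found in 13.1% of resident cells (27.5% without thinning) and in 1.72% and 2.03% of migratory cells, beside 9.43%, 3.39% and 0% of pDC-like cells, and was concentrated in cDC1-like cells (37.7% without SFB, 47.8% with SFB and 34.3% in the resident library). Itgb8 was found in 4.56% and 4.03% of migratory cells (8.82% and 9.55%), near the limits of 5.08% and 3.70% that 0 pDC-like cells allow, and in 0.0228% of resident cells. Tgfb1 lay below its share in pDC-like cells in all 3 libraries and was not read further. Ccr7 was found in 87.4%, 89.96% and 4.72% of cells (91.3%, 95.3% and 8.33% without thinning), beside 30.5%, 51.9% and 3.77% of pDC-like cells. Il12b at 2.70% and 2.51% of migratory cells was close to the 2.47% of pDC-like cells with SFB. Il23a was found in 1, 5 and 1 cells, and Il10 and Saa3 in 0 cells of each library, which allows shares of up to 0.0820%, 0.0801% and 0.0684%. Thinning left out 400, 148 and 88 cells with fewer UMIs.

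**Figure D5:**
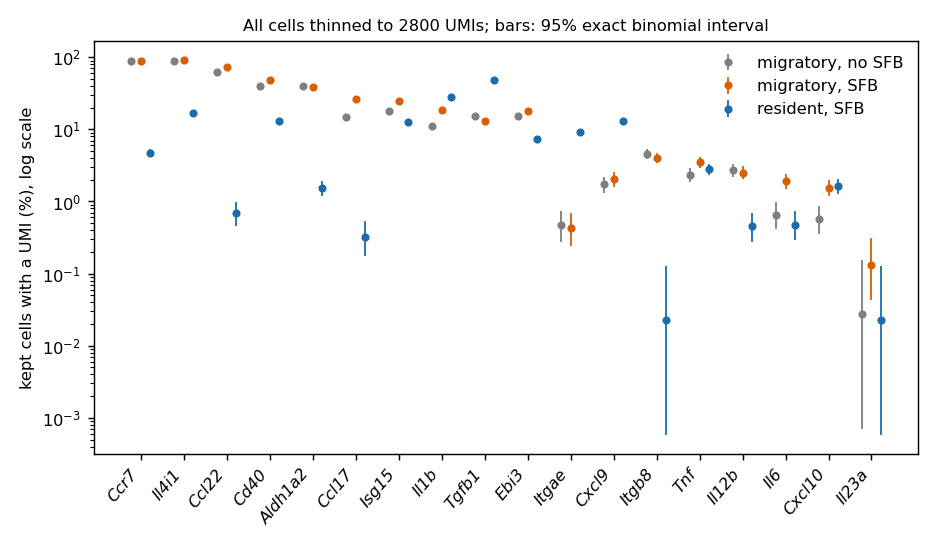
Share of cells (%, log scale) with at least 1 UMI of each gene after thinning all cells to 2800 UMIs, for the migratory libraries without SFB (grey) and with SFB (orange) and the resident library (blue), with 95% exact binomial intervals. Ccl17, Ccl22 and Il1b lie higher with SFB than without, Aldh1a2 does not, and Itgae and Cxcl9 lie highest in the resident library.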

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

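The tests of cell mix, of copies in the genes that have one, of a fault of the SFB library alone, of batch and of free RNA as the source of cells with several of 4 genes were chosen after the results were seen, and the others before. The stricter bounds first set for excluding copies (under 25% with the interval), lower depth (over 2) and deeper cells (over 2) were not met; these exclusions rest on bounds set after the values were seen (under 50%, over 1.5 and over 1), and the bounds for a fault of the SFB library and for handling were made stricter after the values were seen. No paired analysis was possible because each group had 1 library.

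Of 2055 genes at 50 CPM, 20 had a ratio of one sign in all 13 clusters compared between the migratory libraries, 8 of them CCR7-high, and a median ratio of at least 1.5-fold. The 12 higher with SFB included Ccl17, Fabp5, Ifitm1, Gadd45g and Hspa1a, and the 8 lower Rab21, Slc39a1 and Il6st. Free RNA was not tested as a source of the shared shift and stays open. The share of pDC-like cells with Ccl17, read above as background, was itself higher with SFB. A bias of GC content or length was excluded (0.914 of the shift stayed, 95% interval 0.862 to 1.02), as were animals of one sex (0.799) and near-identical copies for the set, of which 25% has one (8.66 to 49.1); the 5 genes with a copy stay open, as the sum with the copies (0.0333 of the shift in the median) rests on 2 genes with far more abundant copies. The mix of clusters was not decided, since the genes were chosen for one sign in every cluster (1.01, 0.846 to 1.22), nor was a fault of the migratory SFB library (0.946), since the resident shift shares its control and in pDC-like cells was 0.83 with an interval of 0.175 to 1.08. A batch that set the library without SFB apart cannot be told apart from colonization (1.42), since both libraries with SFB share the colonization and may share the batch.

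Cells under 1% mitochondrial UMIs made up 21.6% of the library without SFB, 6.70% of the migratory library with SFB and 2.23% of the resident library, mostly shallow CCR7-high cells such as those of cluster 3. Their share was also higher among other classes (5.78% and 1.29%, ratio 4.48, 1.46 to 18.3), as handling of the whole library would likely give. Against this, the same classes had 5.00% in the resident library, and unnamed cells 5.97% without and 7.02% with SFB (ratio 0.850, 0.399 to 1.90), so handling remains open. Lower depth per cell as the whole cause was excluded, because within one depth range the shares were 42.7% and 18.1% (ratio 2.36, 1.79 to 3.14).

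Cells with at least 3 of Il6, Il12b, Il27 and Dll4 numbered 35 of 3303 CCR7-high cells with SFB and 2 of 3160 without. Free RNA may give part of the single transcripts, because the share of cells with Il6 or Il12b in other classes was 0.777 of that in CCR7-high cells (0.403 to 1.37). Free RNA as the source of cells with several of the genes was not decided, since the excess over unlinked genes (ratio 3.78, 2.68 to 5.19) was counted on genes that lead one cluster together. Deeper cells as the whole cause were excluded, since at one depth the shares still differed 3.38-fold (1.59 to 8.02). Doublets were not decided. Of the cluster's cells 3.90% (0.811 to 10.97) were among the top 4% of doublet scores, so the cluster was not rich in high scores. The scores came from the method whose call did not work here, so they cannot exclude doublets.

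Among named genes with at least 50 CPM, 2 were at least 1.5-fold apart in opposite directions in CCR7-high DC-like cells and another class, with both intervals clear of 1. Ifi27l2a had a log2 ratio of -0.93 in ILC3-like and 0.80 in CCR7-high DC-like cells, and Lyz1 of 1.74 in monocyte or macrophage-like and -1.23 in CCR7-high DC-like cells. Within clusters Lyz1 was higher with SFB in 6 of the 8 CCR7-high clusters compared. In the whole libraries 2 cells held 367 of 1381 Lyz1 UMIs without SFB and 472 of 1385 with SFB. The class of these cells was not checked, so a few cells may give much of a Lyz1 ratio, which its interval does not cover. The difference between classes was not tested.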

How the results depend on the processing

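Leaving out the highest doublet scores, the cells under 1% mitochondrial UMIs or the cluster led by Il6, and using CCR7-high cells alone, were chosen after the results were seen. Over the 3 main comparisons 1796 values of named genes were recomputed; 1274 stayed inside the interval, 517 moved out of it and 5 reversed, which counts only ratios at least 1.5-fold apart with an interval clear of 1. In the SFB comparison 464 of 624 stayed and 0 reversed, in the resident comparison 401 of 612 with 2 reversed, and in CCR7-high DC-like cells 409 of 560 with 3 reversed. In the ILC3-like class 178 of 208 stayed and 4 reversed, in the monocyte or macrophage-like class 177 of 192 and in the pDC-like class 200 of 208, with 0 reversed. Where a change of the CPM minimum moved a gene count, the count itself is set by that minimum; for the other settings the cause was not tested.

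For genes higher with SFB in the whole library (8), a 10 CPM minimum gave 32 and 200 CPM 3. For genes lower (9), 10 CPM gave 54, 200 CPM 1, equal weight per cell 5 and one mix of clusters 5. For genes higher in the resident library (667), TMM gave 440, median-ratio scaling 390, totals without ribosomal, mitochondrial and immunoglobulin genes 1002, 10 CPM 1855, 200 CPM 143 and one mix 34. For genes lower (450), 10 CPM gave 897, 200 CPM 151 and one mix 88. At one mix the resident ratios of Cxcl9 (log2 -0.23) and Ube2c (-0.65) reversed. In CCR7-high DC-like cells the genes higher (13) numbered 50 at 10 CPM, 5 at 200 CPM and 6 with each library clustered alone, and those lower (5) 23 at 10 CPM, 0 at 200 CPM and 3 with equal weight per cell.

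With each library clustered alone Il23a (-1.38), Il6 (-0.42) and Selm (-0.13) reversed in the CCR7-high DC-like class, and Il22 (-1.76) and Ly6a (-1.03) in the ILC3-like class. Clusters were then named within each library, so these classes may hold other cells than in the joint clustering. Dnajc9 reversed in the ILC3-like class with all barcodes (0.048) and at resolution 2.0 (0.0063).

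The CCR7-high DC-like share without SFB (77.8%) was 75.6% with all barcodes, 76.3% with doublets kept, 84.1% at resolution 0.5, 81.3% at resolution 2.0, 46.2% with each library alone, 74.5% with 1000 variable genes and 71.5% without cells under 1% mitochondrial UMIs. With SFB (84.8%) it was 76.8% with all barcodes, 86.5% with the stricter filter, 80.2% with doublets kept, 87.5% at resolution 0.5, 83.3% at resolution 2.0, 30.1% with each library alone, 81.9% with 1000 variable genes and 82.4% without the low-mitochondrial cells. Keeping doublets added only 2 cells, so the clusters or their names were unstable at that scale. Another seed gave 77.8% and 84.7%, and the cause was not tested. The resident cDC1-like share (27.3%) was 26.01% with the stricter filter, 29.6% at resolution 2.0, 28.8% with the library alone, 29.4% with 1000 variable genes and 25.9% without the top doublet scores. The resident cDC2-like share (32.5%) was 34.4% with all barcodes, 34.0% with the stricter filter, 40.4% at resolution 0.5, 5.29% with the library alone, 27.8% with 1000 variable genes and 40.8% without low-mitochondrial cells.

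Without thinning, the shares of cells with a UMI without SFB were 1.33% for Il6, 16.9% for Il1b, 57.4% for Aldh1a2, 22.7% for Ccl17 and 75.2% for Ccl22, and with SFB 3.85%, 33.2%, 63.1%, 45.5% and 88.4%. Thinned to 1400 UMIs they were 0.248%, 6.29%, 27.6%, 9.67% and 50.01% without SFB and 1.16%, 12.1%, 25.1%, 18.2% and 57.1% with SFB. In CCR7-high cells alone they were 8.05% for Il1b, 47.1% for Aldh1a2, 17.9% for Ccl17 and 71.7% for Ccl22 without SFB, and 43.2% for Aldh1a2, 28.8% for Ccl17 and 77.9% for Ccl22 with SFB.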

Other observations

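The shares without low-mitochondrial cells were chosen after the results were seen. Il6, Il12b, Il27 and Dll4 are among the leading genes of one cluster and were picked for that. At least 2 of the 4 genes were found in 2.63% of CCR7-high DC-like cells with SFB and 0.696% without, and after thinning in 1.05% and 0.310%. In the other named classes with SFB the share was 2.14% (9 of 420 cells), and 4 of 388 thinned cells (0.282% to 2.62%). At least 3 were found in 1.06% of CCR7-high DC-like cells with SFB and 0.476% of the other named classes (2 of 420 cells). All 4 encode signals to T cells: Il6 and the subunits of IL-12, IL-23 and IL-27 are secreted, and Dll4 is a Notch ligand.

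The low-mitochondrial cells were not confined to CCR7-high cells. They made up 25.8% of CCR7-high DC-like cells without SFB and 7.36% with SFB, and 11.2%, 3.45% and 2.09% of cDC1-like and cDC2-like cells of the library without SFB, the migratory library with SFB and the resident library. The CCR7-high DC-like shares of the migratory libraries were 71.5% and 82.4% without these cells and 75.6% and 76.8% with all barcodes, so the size of their gap depended on the processing. With each library clustered alone they were 46.2% and 30.1%, the only setting that turned the gap. Clusters were named there against the other clusters of the same library, so the turn may come from the naming rule.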
